A study of Homo sapiens with 27 samples.

How the data were processed

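The series holds 27 expression arrays with 49395 probe sets each. Per the labels, EBC-1, MKN-45 and HCC827 cells were given SGX-523 at 1 uM for 24 h or 48 h, or DMSO, with 3 biological replicates per group, and RNA was taken up in TRIZOL, cleaned on columns and labelled with a kit that primes at the 3 prime end. The deposited table gives 1 value per probe set and array on a log2 scale, between 1.87 and 14.39. MAS5 is named per the submitters' processing notes, with no role stated, and how the authors normalized the arrays is not given in the sources used here. The 9 HCC827 arrays seem, from their values, to have been normalized apart from the other 18. The median number of distinct values found on both arrays of a pair, at any probe set, was 1027.5 between HCC827 arrays. It was 1058.5 within EBC-1 or within MKN-45, 1056 between these 2 lines, and 163 between HCC827 and either. The source names of some control arrays count upwards in the name of the cell line, and the groups were taken from the titles. The labels give no batch and no time for the DMSO arrays.

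The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The planned pseudocount of 16 was not applied, since the values were already logarithms. Of the probe sets, 102 were control probe sets, 44988 were annotated to 1 gene, 1832 to several and 2473 to none. Of the single-gene probe sets, 44961 matched the RefSeq table by Entrez ID. A probe set was kept where it reached the median of its array on at least 3 of the 27 arrays, which left 29694, of which 27368 had 1 gene. The kept probe set with the highest mean stood for its gene, and 12390 genes were tested.

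Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on the deposited log2 values, with 9 group means and 18 residual degrees of freedom. The p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and genes past it with at least a 2-fold change were also counted. The comparisons were SGX-523 against DMSO at each time in each line, 48 h against 24 h in each line, the differences between lines in the response at each time, and DMSO of EBC-1 and of MKN-45 against DMSO of HCC827. Overlaps between lists of called genes were set against the number that independent lists would give, and within a line against 100 simulations of groups that share their DMSO arrays. Ratios of control probe sets were compared by exact two-sided permutation, in which 3 against 3 arrays cannot go below 0.1.

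The 27 gene lists were ERK pathway output, G1/S and DNA replication, mitosis, ribosome biogenesis, cholesterol synthesis, glycolysis, ATF4 and amino acid response, ER chaperones, interferon response, MHC class I antigen presentation, chemokines and NF-kB targets, the BCL2 family, FOXO targets and receptor feedback, receptor tyrosine kinases and ligands, mesenchymal genes, epithelial genes, invasion and matrix adhesion, lysosome and autophagy, p53 targets, hypoxia response, oxidative phosphorylation, gastric and intestinal lineage, lung alveolar and airway lineage, squamous lineage, fibroblast, leukocyte and reference genes. Each was tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes and also with the correlation estimated from the arrays. The rotation test fry, which asks whether the genes of a list changed at all, called between 0 and 23 lists in the comparisons with DMSO.

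The named genes were MET, HGF and EGFR, and for each comparison with DMSO the 8 genes with the largest rise and the 8 with the largest fall. These had to be called, to have all treated arrays on the same side of all DMSO arrays, and to have a higher group mean above the median of all genes. From each list the 4 members with the smallest adjusted p were taken. For the genes shared by EBC-1 and MKN-45 the rule took 10 in each direction, ranked by the smaller change of both lines, among those that differed from HCC827 in both. It took 5 in each direction for differences between lines and between times, and the receptor and lineage lists for DMSO. The text uses fewer than the rule takes.

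The alternatives were quantile normalization, centring of each array, pseudocounts of 1 and 64 on the linear scale, no filter, a stricter filter at the 75th percentile of an array, no intensity trend, a separate fit per cell line, the replicate number as a block, the mean of all probe sets of a gene, and each array left out in turn. Array weights, and leaving out HCC827 SGX-523 24 h replicate 3 in comparisons that do not use it, were added after the data were seen. The method was tested on simulated data with 50 genes changed at each of 4 sizes. At 1.25, 1.5 and 2-fold, 44%, 80% and 98% were recovered in a comparison modelled on EBC-1 at 24 h, where 2.42% of the calls were false. Modelled on HCC827 at 24 h, where 1 array stands apart, 15.5% of the calls were false with all 27 arrays and 4% without that array. In 1 simulated comparison with the mitosis list shifted, that list was called and so was 1 list that had not been shifted, gastric and intestinal lineage (adjusted p = 0.0357). Probe sets with several genes or none were left out of the gene tests and counted apart. No other data type was analysed here.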

Results

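Gene expression was measured on 27 one-colour arrays of 3 human cancer cell lines, with 3 arrays in each of 9 groups. Per the labels, EBC-1 (non-small cell lung cancer) and MKN-45 (a gastric cancer line) depend on the receptor tyrosine kinase MET, and HCC827 (non-small cell lung cancer) carries active c-Met without depending on it. Each line received SGX-523, a small-molecule inhibitor of the MET kinase, at 1 uM for 24 h or 48 h, or DMSO, its solvent. The labels give no time for the DMSO arrays, so both times were compared with the same 3 DMSO arrays of a line. After a filter on low signal, 12390 genes were tested, each by 1 probe set. Deposited log2 values ran from 1.87 to 14.39, and the number of arrays limits the precision. The median standard error of a difference between groups was 0.11 log2 units. Where the lower group level lies under the array median, the size of a change is less certain than its direction. The labels call the 3 arrays of a group biological replicates. The p-values and SE rest on the spread between such arrays, pooled over all 9 groups. It includes that of HCC827 SGX-523 24 h replicate 3, an array that stood apart, also in comparisons of EBC-1 and MKN-45. Unless stated otherwise, gene values are log2 fold changes, SGX-523 minus DMSO, ± SE with n = 3 arrays per group. A gene was called where its limma p, adjusted by Benjamini-Hochberg over all genes, was under 0.05.

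The 9 HCC827 arrays had medians of 5.71 to 5.73, against 5.02 to 5.14 on the 18 arrays of EBC-1 and MKN-45. Pairs made of an HCC827 array and an array of another line shared a median of 163 distinct values, found at any probe set. Pairs of EBC-1 with MKN-45 arrays shared 1056 and pairs of HCC827 arrays 1027.5. Levels compared between HCC827 and the other lines may therefore carry a difference in normalization. Within groups, Pearson's r across probe sets was at least 0.9958, apart from HCC827 at 24 h. There, replicate 3 had r between 0.962 and 0.967 with the other HCC827 arrays, while the other 8 had at least 0.99285 with each other. Its residual SD was 0.367, against at most 0.115 on the arrays outside its group.

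**Figure D1:**
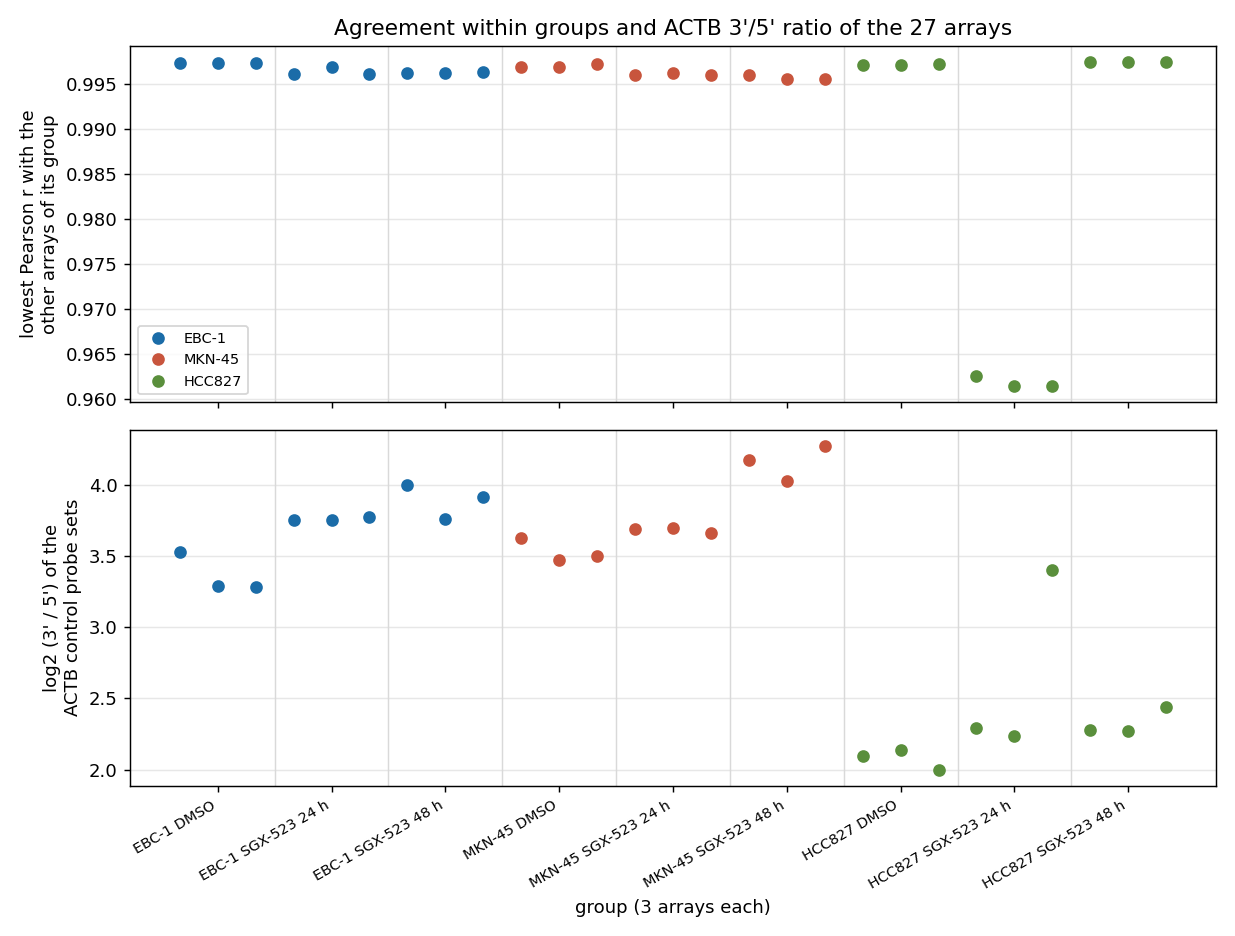
Lowest Pearson correlation of each of the 27 arrays with the other arrays of its group (top) and the log2 ratio of the 3 prime to the 5 prime ACTB control probe sets (bottom), 1 point per array. HCC827 SGX-523 24 h replicate 3 has a log2 ratio of 3.404, against at most 2.44 on the other 8 HCC827 arrays.

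The transcript of the drug target itself fell in the lines that depend on it. By its brightest probe set, MET changed with SGX-523 in EBC-1 by -0.48 ± 0.14 at 24 h (adjusted p = 0.00552) and by -0.63 at 48 h (adjusted p = 4e-04). In MKN-45 the values were -0.49 (adjusted p = 0.00437) and -0.52 (adjusted p = 0.00257). Of the 6 MET probe sets kept, 5 were called lower in each of these 4 comparisons. At 48 h the other 4 of these were at -0.83 to -1.07 in EBC-1 and at -1.49 to -1.55 in MKN-45, further than the brightest. The remaining MET probe set was lower by -0.41 to -0.68 in these comparisons and was not called. Its SD was at most 0.085 in the groups of EBC-1 and MKN-45. In HCC827 at 24 h, which enters the shared spread, it was 1.19. In HCC827, MET was -0.19 ± 0.14 at 24 h (adjusted p = 0.405) and 0.018 ± 0.14 at 48 h (adjusted p = 0.953). The 24 h value rests on the aberrant replicate 3 of HCC827 SGX-523 24 h. Without replicate 3, MET was at 0.099 (adjusted p = 0.949), and without replicate 2, which leaves replicate 3 as 1 of 2 treated arrays, it was called at -0.40 (adjusted p = 0.0323). EGFR, the receptor of epidermal growth factor, rose in EBC-1 (0.69 ± 0.057 at 24 h, 1.21 at 48 h) and fell in MKN-45 (-0.63 and -1.34). It was called in neither comparison in HCC827 (0.037 and 0.061, adjusted p = 0.708 and 0.521), where its DMSO level was 11.99 ± 0.044 (SD, n = 3). The 4 probe sets of HGF, the ligand of MET, stayed below the array median on every array and were not tested.

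**Figure D2:**
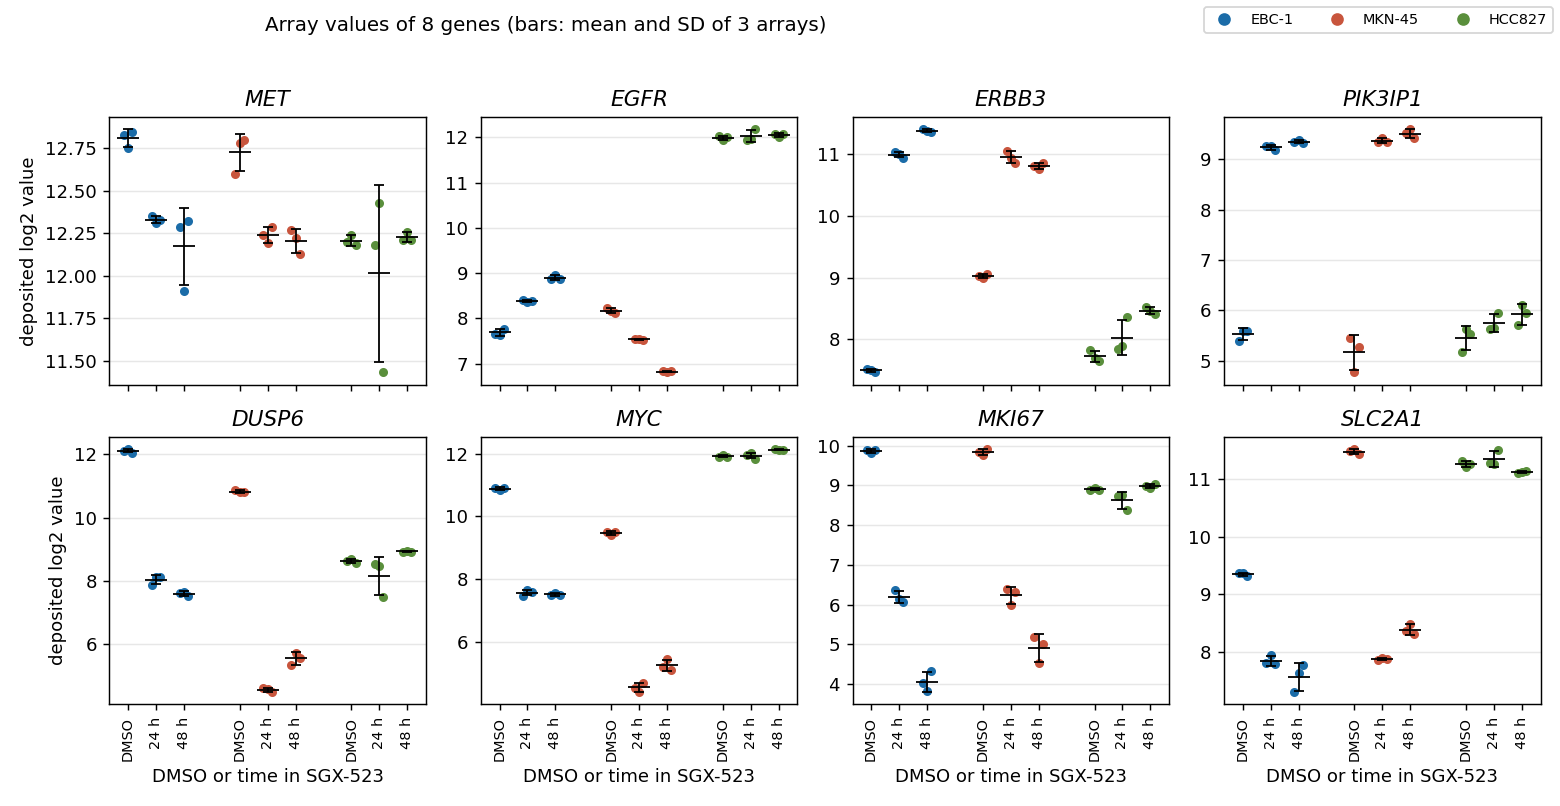
Deposited log2 values of 8 genes on each array, by cell line and arm, with the mean and SD of 3 arrays. DUSP6 fell in EBC-1 and MKN-45, with log2 fold changes at 24 h of -4.07 and -6.26, and was not called in HCC827.

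The first question was what blocking MET does in EBC-1, a line that depends on it. At 24 h, RRM2, a subunit of ribonucleotide reductase, changed by -6.00 ± 0.11 (adjusted p = 3.15e-23), from a DMSO level of 10.73 ± 0.013 (SD, n = 3), and fell most of the named genes. SPC25 of the kinetochore (-5.64), SHCBP1 (-5.27), the ETS factor ETV5 (-5.22), UHRF1 of DNA methylation maintenance (-5.07), MYEOV (-4.82), the replication licensing factor CDC6 (-4.67) and the mitotic kinase CDK1 (-4.53) also fell. The treated level of RRM2, 4.73 ± 0.15, lay under the array medians. Among the largest rises were HPGD, which degrades prostaglandins (4.37 ± 0.077), the actin-severing SCIN (4.32), the cholesterol exporter ABCA1 (4.17) and TP53INP1 (4.08). PIK3IP1, an inhibitor of PI3 kinase (3.72), the death ligand TNFSF10 (3.71), BNIP5 (3.70) and the selenium carrier SELENOP (3.63) also rose.

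By gene list at 24 h in EBC-1, 17 of 19 ERK output genes fell and 0 rose, with a median of -3.26 (camera adjusted p = 3.13e-13). Among them were EPHA2 (-3.56), cyclin D1 gene CCND1 (-3.49), the ERK phosphatase gene DUSP4 (-4.22) and MYC (-3.31). All 24 mitosis genes fell (median -3.14, adjusted p = 2.44e-20), for example UBE2C (-3.19) and TOP2A (-3.15), as did 23 of 24 genes of G1/S and replication (median -2.28, adjusted p = 1.94e-16), for example GINS1 (-2.76) and TYMS (-3.16). All 22 ribosome biogenesis genes fell (median -1.66, adjusted p = 2.29e-14), among them NOLC1 (-1.96) and LYAR (-2.85). Glycolysis genes fell in 12 of 16 cases and rose in 3 (median -0.87, adjusted p = 0.000111), with ENO1 at -1.88 and PKM at -1.68. In the list of ATF4 and amino acid genes 14 of 25 fell and 5 rose (median -0.45, adjusted p = 0.00534), led by the serine synthesis gene PSAT1 (-3.05). Matrix and invasion genes included 8 lower and 2 higher of 15 (median -0.31, adjusted p = 0.0281), with the collagenase MMP1 at -4.43. With an estimated correlation that adjusted p was 0.0371, and 0.0513 without HCC827 SGX-523 24 h replicate 3, which changes the spread shared by all groups. ER chaperones fell in 12 of 16 cases and rose in 2 (adjusted p = 0.000278, and adjusted p = 0.137 with an estimated correlation), with MANF at -1.77. Without HCC827 SGX-523 24 h replicate 3, the estimated correlation gave 0.0492 for this list, which passes. Hypoxia genes fell in 8 of 12 cases and rose in 2 (adjusted p = 0.0406, and adjusted p = 0.142 with an estimated correlation), and without EBC-1 DMSO replicate 3 the adjusted p was 0.0501.

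The lists that rose in EBC-1 at 24 h were those of FOXO targets, antigen presentation and lysosomes. Of the FOXO targets and receptor feedback genes, 15 of 18 rose and 1 fell (median 1.87, adjusted p = 7.72e-09), among them TXNIP (2.01), the receptor gene ERBB3 (3.49), BCL6 (2.03) and FOXO3 (1.86). MHC class I genes rose in 12 of 13 cases and fell in 1 (median 0.95, adjusted p = 0.000119), with HLA-C at 1.05 and TAPBP at 1.52. Lysosome and autophagy genes rose in 17 of 20 cases and fell in 2 (median 0.68, adjusted p = 0.000119), with CTSA at 1.75. Reference genes, often used as constant, fell in 7 of 8 cases and rose in 1 (median -0.56, adjusted p = 0.00534), with ACTB at -1.41 and HPRT1 at -1.10. On the same arrays the median of 42 external control probe sets was higher by 0.377, and the log2 3 prime to 5 prime ratio of ACTB was 3.76 ± 0.014 (SD, n = 3) against 3.36 ± 0.14 in DMSO (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). The oxidative phosphorylation list was not called (7 lower and 1 higher of 15, adjusted p = 0.0584), but was without EBC-1 DMSO replicate 3 (adjusted p = 0.0424). Adjusted over a list alone, 1 more member was called in the ATF4, ER chaperone and invasion lists, and as many as above in the other 10 called lists. A total of 7336 genes were called at 24 h, 3861 higher and 3475 lower, of which 955 and 1011 changed at least 2-fold. Of the 27 lists, 13 were called, and 11 of them with an estimated correlation.

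At 48 h in EBC-1 the mitotic genes had fallen further and the detoxification gene GSTA1 led the rises. RRM2 was at -6.58 ± 0.11 (adjusted p = 2.45e-24), the centromere histone gene CENPA at -6.18, CDK1 at -6.15, SHCBP1 at -6.13 and SPC25 at -6.05. The spindle gene DLGAP5 (-5.98), the condensin subunit gene NCAPG (-5.90) and the proliferation marker MKI67 (-5.81) completed the largest falls. GSTA1 rose by 5.11 ± 0.12 and GSTA2 by 4.51, both glutathione transferases, beside SCIN (4.88), HPGD (4.76), TP53INP1 (4.33), SELENOP (4.15), RARRES1 (4.11) and BNIP5 (3.93).

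The list medians at 48 h in EBC-1 were -4.26 for mitosis (24 of 24 lower, adjusted p = 2.81e-22) and -2.92 for ERK output (18 of 19 lower, adjusted p = 1.83e-12), with DUSP4 at -4.07. G1/S and replication had 23 of 24 lower (median -2.64, adjusted p = 3.68e-16), with TYMS at -4.06, and ribosome biogenesis 22 of 22 (median -1.63, adjusted p = 4.64e-14), with NOP16 at -2.39. Glycolysis (12 lower and 2 higher of 16, adjusted p = 0.000156), the ATF4 list (15 lower and 6 higher of 25, adjusted p = 0.00314) and the invasion list (9 lower and 2 higher of 15, adjusted p = 0.0021) were again lower, with CD44 at -2.55. FOXO targets (16 of 18 higher, median 1.82, adjusted p = 1.46e-08), MHC class I (11 of 13, 0.90, adjusted p = 0.000169) and lysosome genes (15 of 20, 0.76, adjusted p = 0.000156) were again higher, with ERBB3 at 3.88. Cholesterol synthesis genes rose in 11 of 15 cases and fell in 1 (median 0.34, adjusted p = 0.0238), among them MSMO1 (1.56) and INSIG1 (1.24). With the mean of all probe sets of each gene that adjusted p was 0.0527. With an estimated correlation it was 0.0337, and 0.0746 without HCC827 SGX-523 24 h replicate 3. The falls of the ER chaperones (12 of 16, adjusted p = 0.000214) and of oxidative phosphorylation (12 of 15, adjusted p = 0.00672) were lost with an estimated correlation (adjusted p = 0.111 and adjusted p = 0.102 with an estimated correlation). Without HCC827 SGX-523 24 h replicate 3, the estimated correlation gave 0.0386 for the ER chaperones, which passes, and 0.238 for oxidative phosphorylation. Reference genes were lower in 7 of 8 cases (median -0.42, adjusted p = 0.00422), on arrays where the external controls were higher by 0.423 and the ACTB ratio was 3.89 ± 0.12 (SD, n = 3; exact permutation p = 0.1). Adjusted over the list alone, 1 more member was called in the G1/S and MHC class I lists and as many in the other 12. Called genes numbered 7632, with 4057 higher and 3575 lower, of which 1024 and 1104 changed at least 2-fold, and 14 lists were called, 12 of them with an estimated correlation. Of the called genes, 6625 were called the same way at both times and 11 the opposite way. Independent lists would give 2267 the same way. A simulation of unchanged groups against the shared DMSO arrays gave 0 on average over 100 runs. No change was put in, so hardly any gene could be called in it, and that 0 adds no support. The covariance of the fold changes was 0.708 against 0.00747 simulated, and the 3 DMSO arrays were too few to be split between the times.

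In MKN-45, the gastric line that depends on MET, FOS and DUSP6, both in the ERK output list, fell most of the named genes at 24 h. FOS, an AP-1 subunit gene, changed by -6.77 ± 0.23 (adjusted p = 5.79e-18) from a DMSO level of 10.05 ± 0.16 (SD, n = 3), and DUSP6, the ERK phosphatase gene, by -6.26 ± 0.16. Their treated levels of 3.29 ± 0.35 and 4.56 ± 0.063 lie under the array medians, so these sizes are uncertain. SPC25 (-5.37), the ETS factors ETV5 (-5.23) and ETV1 (-5.21), the hyaluronan-binding CEMIP (-5.14), EMP1 (-5.03) and MYC (-4.92) came next. The trypsin inhibitor gene SPINK1 rose most (5.97 ± 0.088), ahead of GSTA1 (5.86), the glucuronosyltransferase gene UGT2B15 (5.84), the stress gene NUPR1 (5.79), ANO3 (5.37), TMED6 (4.98), GSTA2 (4.81) and TNFRSF19 (4.68).

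In the ERK output list 18 of 19 genes fell at 24 h in MKN-45 and 1 rose (median -2.58, adjusted p = 1.02e-14). The one that rose was EPHA4 (0.62), named here after its value was seen. All 24 mitosis genes (median -3.04, adjusted p = 3.47e-21) and all 24 of G1/S and replication (median -2.44, adjusted p = 6.14e-19) fell, with TOP2A at -3.05 and MCM4, a replicative helicase subunit gene, at -3.45. Ribosome biogenesis genes fell in 21 of 22 cases (median -0.95, adjusted p = 8.51e-11), with LYAR at -2.23, and glycolysis genes in 15 of 16 (median -1.83, adjusted p = 3.6e-13), with the glucose transporter gene SLC2A1 at -3.58 and PKM at -2.90. ATF4 and amino acid genes (18 lower and 3 higher of 25, adjusted p = 4.95e-05) were lower, with DDIT4 at -2.01. So were hypoxia genes (8 and 2 of 12, adjusted p = 0.00454) with PDK1 at -2.16, invasion genes (8 and 3 of 15, adjusted p = 0.0117) with ITGB4 at -2.51, and oxidative phosphorylation (12 and 0 of 15, adjusted p = 0.00095). With an estimated correlation the last had adjusted p = 0.0446, lost without HCC827 SGX-523 24 h replicate 3 (adjusted p = 0.128). Cholesterol synthesis fell by its preset test (8 lower and 1 higher of 15, adjusted p = 0.0431), with adjusted p = 0.0506 with an estimated correlation. That adjusted p was 0.0647 without MKN-45 DMSO replicate 1 and 0.0646 without MKN-45 SGX-523 24 h replicate 3.

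FOXO targets rose in 12 of 18 cases and fell in 3 at 24 h in MKN-45 (median 0.49, adjusted p = 0.00169), with PIK3IP1 at 4.21, BCL6 at 2.45 and TXNIP at 1.94. MHC class I genes rose in 12 of 13 cases (median 0.64, adjusted p = 0.000814), with HLA-E at 1.77 and PSMB9 at 1.37, and lysosome genes in 14 of 20 (median 0.39, adjusted p = 0.00601, and adjusted p = 0.0739 with an estimated correlation), with WIPI1 at 1.79. Reference genes fell in 6 of 8 cases (median -0.39, adjusted p = 0.00711), with HPRT1 at -1.92 and ACTB at -1.53, while GUSB rose (0.42). The external controls were higher by 0.352 on these arrays, and the ACTB 3 prime to 5 prime ratio was 3.68 ± 0.020 (SD, n = 3) against 3.53 ± 0.084 in DMSO (exact permutation p = 0.1). Adjusted over the list alone, 1 more member was called in the FOXO and oxidative phosphorylation lists and as many in the other 12. Called genes numbered 7470, with 4140 higher and 3330 lower, of which 1012 and 881 changed at least 2-fold, and 14 lists were called, 12 of them with an estimated correlation.

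At 48 h in MKN-45, SPINK1 (6.77 ± 0.088) and GSTA1 (6.58 ± 0.12) were again the genes that rose most, joined by the neuroendocrine factor gene INSM1 (5.84) and the G protein regulator gene RGS4. UGT2B15 (5.78), TMED6 (5.38), the matrix gene MATN2 (5.30) and TNFRSF19 (5.30) followed. FOS was at -6.23 ± 0.23, SPC25 at -5.95, EMP1 at -5.88, DLGAP5 at -5.37, the cytokinesis gene CEP55 at -5.32, DUSP6 at -5.27, AKAP12 at -5.26 and CEMIP at -5.19.

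Mitosis genes were lower in 24 of 24 cases at 48 h (median -3.72, adjusted p = 3.07e-23), G1/S and replication in 24 of 24 (-2.12, adjusted p = 1.03e-18), and ERK output in 18 of 19 (-2.44, adjusted p = 4.52e-13), with CCNB2 at -3.81 and MYC at -4.22. Glycolysis fell in all 16 members (median -2.16, adjusted p = 3.5e-14), among them PGK1 (-2.13) and LDHA (-2.18), and ribosome biogenesis in 20 of 22 (-0.89, adjusted p = 8.28e-10). The ATF4 list (18 lower and 3 higher of 25, adjusted p = 4.13e-05), the invasion list (8 and 3 of 15, adjusted p = 0.0121) and oxidative phosphorylation (13 and 1 of 15, adjusted p = 0.000214) were lower. The last had adjusted p = 0.0281 with an estimated correlation, and 0.0978 without HCC827 SGX-523 24 h replicate 3. Hypoxia genes were lower by the preset test (8 and 3 of 12, adjusted p = 0.0152), with adjusted p = 0.0816 with an estimated correlation. Without HCC827 SGX-523 24 h replicate 3, the estimated correlation gave 0.0395 for this list, which passes. FOXO targets (13 higher and 3 lower of 18, adjusted p = 0.000809) with INSR at 2.38, MHC class I (12 and 1 of 13, adjusted p = 0.000104) and lysosome genes (16 and 1 of 20, adjusted p = 0.0011) were higher. Reference genes were lower in 6 of 8 cases (median -0.42, adjusted p = 0.00659), beside external controls higher by 0.267 and an ACTB ratio of 4.16 ± 0.12 (SD, n = 3; exact permutation p = 0.1). Adjusted over the list alone, 1 more member was called in the invasion list and as many in the other 12. Called genes numbered 7757, with 4514 higher and 3243 lower, of which 1265 and 879 changed at least 2-fold, and 13 lists were called, 12 of them with an estimated correlation. Both times called 6428 genes the same way and 69 the opposite way, where independent lists would give 2380 the same way. The covariance of the fold changes was 0.706 against 0.00749 in the simulation with shared DMSO arrays. Its count of 0 was again fixed by its setting.

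**Figure D3:**
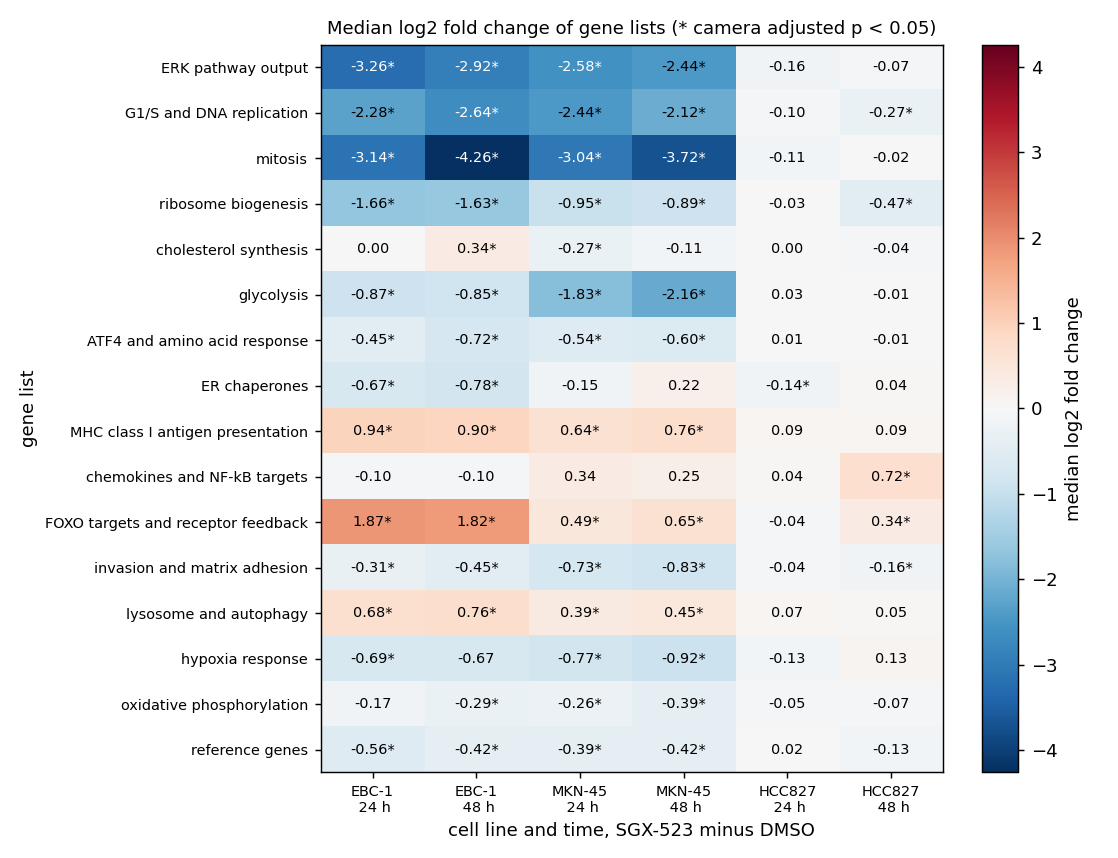
Median log2 fold change, SGX-523 minus DMSO, of the gene lists called in at least 1 of the 6 comparisons. Asterisks mark lists past the camera test, and mitosis has medians of -4.26 in EBC-1, -3.72 in MKN-45 and -0.021 in HCC827 at 48 h.

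HCC827 served as the line with active c-Met that does not depend on it. At 24 h, 4 genes were called and all were higher, by limma. Named because they were so few, after their values were seen, they were the transcription factor gene SOX4 (0.26 ± 0.038, adjusted p = 0.0088), the aldo-keto reductase gene AKR1C3 (0.24 ± 0.045, adjusted p = 0.0455), TMT1A (0.50, adjusted p = 0.0455) and VWA5A (0.39, adjusted p = 0.0455). Without HCC827 DMSO replicate 2, 0 genes were called, so all 4 were lost (adjusted p = 0.0845 for SOX4 and for AKR1C3). Without DMSO replicate 3, 1 gene was called, and SOX4 and AKR1C3 were lost (adjusted p = 0.0627 and 0.321). AKR1C3 was also lost without DMSO replicate 1 (adjusted p = 0.0944). None of the 4 changed 2-fold, while 2614 genes had an unadjusted p under 0.05. ERK output genes were called in 0 of 19 cases (median -0.16, adjusted p = 0.0528; 2 adjusted over the list alone), as were mitosis genes in 0 of 24 (median -0.11, adjusted p = 0.371) and FOXO targets in 0 of 18 (median -0.036, adjusted p = 0.961). ER chaperones were the list called (median -0.14, adjusted p = 0.039, and adjusted p = 0.649 with an estimated correlation), with adjusted p of 0.0531 without DMSO replicate 2 and 0.126 without treated replicate 2. These values depend on replicate 3 of the treated group, which had an ACTB 3 prime to 5 prime ratio of 3.404. Without it, 768 genes had an unadjusted p under 0.05 and 20 were called, 18 higher and 2 lower, the 4 above among them, and with, among the others and chosen after their values were seen, the tetraspanin gene TSPAN8 at 0.55 (adjusted p = 1.88e-07), VAV3 at 0.67 (adjusted p = 2.06e-07) and AGR2, a disulfide isomerase gene, at 0.38 (adjusted p = 4.09e-06). The ER chaperone median was then -0.018 (adjusted p = 0.279), and the lists of ERK output (-0.12, adjusted p = 0.0117), interferon response (-0.17, adjusted p = 7.56e-07), chemokines (0.14, adjusted p = 0.0194) and oxidative phosphorylation (-0.078, adjusted p = 1.84e-06) passed the preset test. By limma 0 members of these 4 lists were called, and none of the 4 held with an estimated correlation (adjusted p = 0.275 for ERK output and 0.139 for each of the others). Without treated replicate 1 or 2, which leaves replicate 3 as 1 of 2 arrays, 2394 and 2675 genes were called, of which 758 and 824 were higher, and without DMSO replicate 2 or 3 the numbers were 0 and 1.

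At 48 h in HCC827 the acute phase gene SAA1 was at 2.14 ± 0.13 (adjusted p = 4.41e-11) from a DMSO level of 5.91 ± 0.25 (SD, n = 3), S100P at 2.12, TSPAN8 at 1.82, the chemokine gene CCL20 at 1.81, the immediate early gene EGR1 at 1.75, AGR2 at 1.73, S100A9 at 1.66 and the fibrinogen gene FGB at 1.60. Among the genes that fell were TMEM158 (-1.12 ± 0.11), the gelatinase gene MMP9 (-1.07), the RNA polymerase III gene POLR3G (-0.95), AFAP1L2 (-0.93), CHAC2 (-0.89), the polyamine synthesis gene ODC1 (-0.89), NEXN (-0.88) and the cyclin gene CCNE2 (-0.86).

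Ribosome biogenesis genes fell in 20 of 22 cases at 48 h in HCC827 (median -0.47, adjusted p = 8.67e-15), with TSR1 at -0.52 and RRP12 at -0.62. G1/S and replication genes fell in 12 of 24 cases (18 adjusted over the list alone, median -0.27, adjusted p = 7.59e-08), with MCM3 at -0.43. Mitosis genes had 3 higher and 1 lower of 24 (adjusted p = 0.945), with a median of -0.021 and a mean of 0.00039 that differed in sign. Chemokine and NF-kB target genes rose in 9 of 15 cases and fell in 1 (13 adjusted over the list alone, median 0.72, adjusted p = 3.47e-06), among them CXCL8 (1.03), CXCL1 (0.74) and NFKBIA (0.47). FOXO targets rose in 11 of 18 cases and fell in 1 (13 adjusted over the list alone, median 0.34, adjusted p = 9.1e-06), with BCL6 at 1.15 and INSR at 0.67. Invasion genes fell in 6 of 15 cases and rose in 1 (median -0.16, adjusted p = 0.00684), with MMP1 at -1.91. ERK output genes had 3 higher, EGR1, FOS (1.52) and IER3 (0.48), and 5 lower, with CCND1 at -0.55. That list's median of -0.073 and mean of 0.046 differed in sign, and it was not called (adjusted p = 0.662). The 5 called lists held with an estimated correlation. The ACTB ratio was 2.33 ± 0.096 (SD, n = 3) against 2.08 ± 0.071 in DMSO (exact permutation p = 0.1), and the external controls differed by -0.038. Called genes numbered 2755, with 1433 higher and 1322 lower, of which 72 and 7 changed at least 2-fold. Without the aberrant 24 h array, which widens the spread estimate shared by all groups, 4649 genes were called. All 4 genes called at 24 h were called at 48 h the same way, against 0.463 from independent lists. Without the aberrant array the number was 18. Both times were compared with the same DMSO arrays, so the lists are not independent and 0.463 is not a like standard. The simulation of unchanged groups gave 0, which its setting fixed in advance. The covariance of the fold changes was 0.0138 against 0.00751 simulated, and their correlation was 0.254 against 0.5 simulated. The simulation gave all arrays the same spread and left out the wider one of the aberrant array (residual SD 0.367). The correlations are therefore not a like comparison. Whether the times share a response was not resolved with all arrays.

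A central comparison asked which changes EBC-1 and MKN-45 share and HCC827 lacks. At 24 h, GSTA1 (4.29 in EBC-1 and 5.86 in MKN-45), PIK3IP1 (3.72 and 4.21), ABCA1 (4.17 and 3.60), TP53INP1 (4.08 and 3.57) and BNIP5 (3.70 and 3.55) rose in both and differed from HCC827 in both. N4BP2L1, TNFSF10, GSTA2, UGT2B15 and SELENOP were next in size. SPC25 (-5.64 and -5.37), ETV5 (-5.22 and -5.23), ETV1 (-4.52 and -5.21), the ubiquitin ligase gene DTL (-4.16 and -4.41) and SHCBP1 (-5.27 and -4.16) fell in both, followed by RRM2, CDC45, DUSP6, FAM111B and PBK. The SE was 0.12 for GSTA1 and 0.12 for SPC25, with n = 3 per group. At 48 h the shared falls were led by SPC25, DLGAP5 (-5.98 and -5.37), KIF20A (-5.15 and -5.06), RRM2, MKI67, CENPA, NEK2, CEP55, ASPM and BIRC5, and the shared rises by GSTA1 (5.11 and 6.58), GSTA2, TP53INP1, UGT2B15, PIK3IP1, SPINK1 and KRT15 (3.17 and 4.03).

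Counted over all genes, 4920 were called the same way in EBC-1 and MKN-45 at 24 h (2599 higher, 2321 lower) and 627 in opposite ways, where independent lists would give 2224 the same way. At 48 h the numbers were 4819 (2651 higher, 2168 lower), 852 and 2414. Across genes, which are not independent replicates, the fold changes of the lines correlated with Pearson r = 0.649 and Spearman rho = 0.625 at 24 h, and with 0.598 and 0.555 at 48 h. Of the shared genes, 3825 at 24 h and 3066 at 48 h also differed from HCC827 in both lines in that direction, 2527 of them at both times. At 48 h, 1522 of the shared genes were called in HCC827 as well, and 1362 of these (89.5%) in the same direction. Over the 3066 genes that differed from HCC827, the medians in HCC827 were 0.045 for those higher and -0.085 for those lower. These genes were chosen for differing from HCC827, so the medians do not describe all shared genes. The fold changes of HCC827 correlated across genes with those of EBC-1 with r = 0.109 and rho = 0.0996 at 24 h and r = 0.383 and rho = 0.434 at 48 h. With those of MKN-45 they did with r = 0.0592 and rho = 0.0324 at 24 h and r = 0.25 and rho = 0.282 at 48 h. The 24 h values include the aberrant array.

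**Figure D4:**
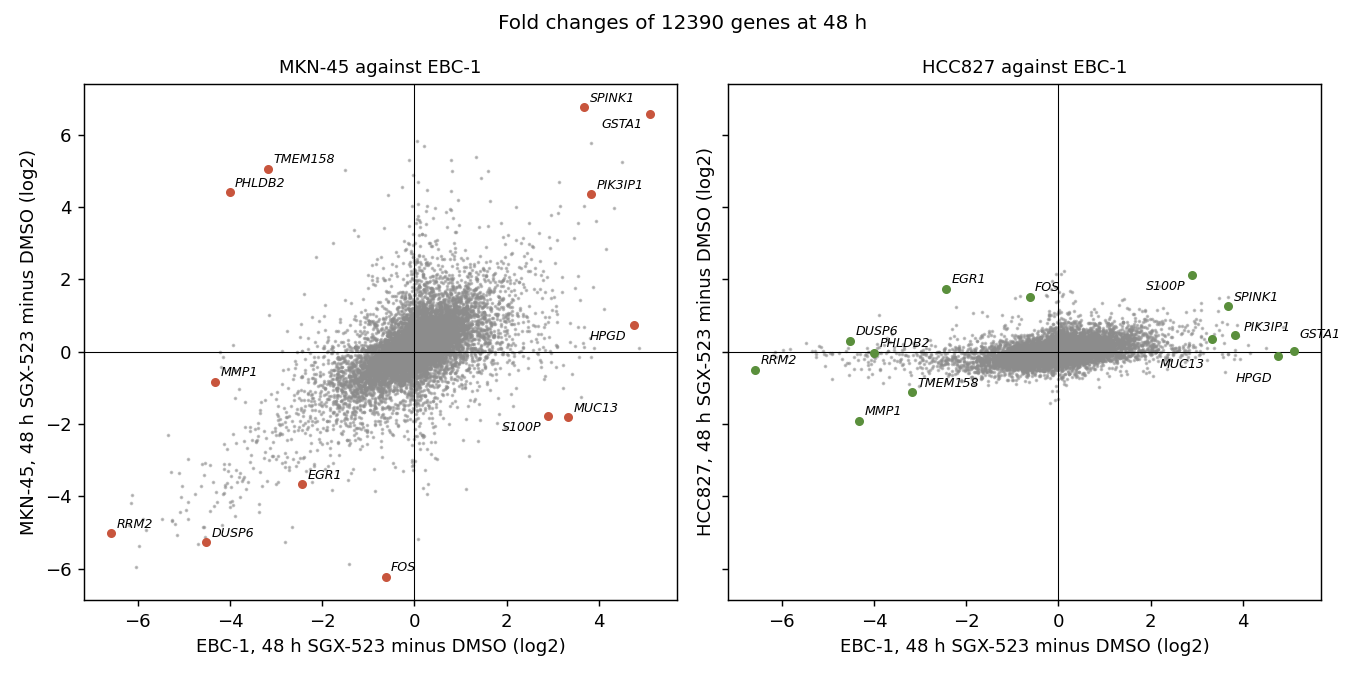
Log2 fold changes of 12390 genes at 48 h, SGX-523 minus DMSO, in MKN-45 (left) and HCC827 (right) against EBC-1, with named genes marked. Pearson r across genes is 0.598 for MKN-45 and 0.383 for HCC827.

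Differences in response between the lines were tested as interactions, with 3 arrays per group. Against HCC827 at 24 h, the difference for RRM2 in EBC-1 was -6.02 ± 0.15, for SPC25 -5.66, for SHCBP1 -5.33, for ABCA1 4.29, for HPGD 4.25 and for GSTA1 4.19. In MKN-45 it was -6.65 ± 0.33 for FOS, -5.80 for DUSP6, -5.56 for CEMIP, 5.80 for UGT2B15 and 5.59 for SPINK1. Among the largest at 48 h were CDK1 (-6.16), CENPA (-6.09), GSTA1 (5.09) and GSTA2 (4.42) for EBC-1, and FOS (-7.74), EMP1 (-6.13), GSTA1 (6.56), RGS4 (6.27) and TMEM158 (6.19) for MKN-45. By its brightest probe set, MET itself differed from HCC827 at 48 h (EBC-1 -0.65, adjusted p = 0.00914; MKN-45 -0.54, adjusted p = 0.0281) and was not called at 24 h (adjusted p = 0.257 and 0.227). Without HCC827 SGX-523 24 h replicate 3 it was called at 24 h too (EBC-1 -0.58, adjusted p = 1.15e-05; MKN-45 -0.59, adjusted p = 8.14e-06). The lists of mitosis (interaction medians -4.19 and -3.69), G1/S and replication (-2.29 and -1.92) and ERK output (-2.84 and -2.36) were lower in EBC-1 and MKN-45 than in HCC827 at 48 h, with camera adjusted p of 3.65e-29, 1.53e-28, 3.22e-18, 1.72e-19, 1.87e-15 and 1.18e-14, and held with an estimated correlation. Genes with a called difference numbered 6390 (3492 higher, 2898 lower) at 24 h and 6031 (3038 and 2993) at 48 h for EBC-1, and 6525 (3767 and 2758) and 6328 (3663 and 2665) for MKN-45. The share of higher genes for MKN-45 at 24 h, 57.7%, depended on the scaling and was 46.8% with each array centred.

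Between EBC-1 and MKN-45 the response of 5218 genes differed at 24 h (2273 higher in EBC-1, 2945 lower) and of 6075 at 48 h (2433 and 3642). The shares higher in EBC-1, 43.6% and 40%, were 51.7% and 49.6% with each array centred, so which direction held more genes at 24 h depended on the scaling. At 48 h the largest differences were the cytoskeletal gene PHLDB2 (-8.41 ± 0.17), which fell in EBC-1 (-4.01) and rose in MKN-45 (4.41), TMEM158 (-8.24), ANO3 (-6.55), INSM1 (-5.78) and RGS4 (-5.50). In the other direction were FOS (5.60 ± 0.33), IQGAP2 (5.37), CEMIP (5.28), the mucin gene MUC13 (5.15) and ADGRF1 (4.92). FOS was at -6.23 in MKN-45 and at -0.63 in EBC-1, where it was not called without DMSO replicate 2 (adjusted p = 0.0598), 48 h replicate 1 (adjusted p = 0.0606) or 48 h replicate 3 (adjusted p = 0.0533). Glycolysis genes fell further in MKN-45, with interaction medians of 0.95 at 24 h (15 of 16 genes called, adjusted p = 7.96e-13) and 0.98 at 48 h (16 of 16, adjusted p = 6.18e-12). Ribosome biogenesis genes fell further in EBC-1 (-0.63 and -0.78, adjusted p = 1.36e-06 and 1.52e-06). Gastric and intestinal lineage genes were relatively higher in EBC-1 (0.75 and 0.65, adjusted p = 0.00129 and 0.00197), where MUC13 rose (3.33) and the trefoil peptide gene TFF1 was at 0.19 (adjusted p = 0.233), against -3.76 in MKN-45. The EBC-1 DMSO level of TFF1, 3.48 ± 0.11 (SD, n = 3), lay under the array medians, as did those of TFF2, TFF3, PGC and CDX1. A fall of these genes could hardly show in EBC-1. Cholesterol synthesis differed at 48 h (0.82, adjusted p = 3.31e-05) and at 24 h (0.27, adjusted p = 0.0416, and adjusted p = 0.074 with an estimated correlation). FOXO targets were higher in EBC-1 at 48 h by the preset test (0.55, adjusted p = 0.00197, and adjusted p = 0.0807 with an estimated correlation), as chemokine genes were lower (-1.19, adjusted p = 0.000882, and adjusted p = 0.0507 with an estimated correlation).

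The comparison of 48 h with 24 h asked what changed while the inhibitor stayed on. The labels give no time for the DMSO arrays, so changes with time in culture could not be separated from those with the inhibitor. The genes that fell in EBC-1 were led by the replication factor gene PCLAF at -2.52 ± 0.058 (48 h minus 24 h), TOP2A at -2.32, KIF20A at -2.24, MKI67 at -2.14 and BIRC5 at -2.00. TMIGD1 (1.92), the guanylate cyclase gene GUCY2C (1.77), BAMBI (1.45), KCNJ13 (1.43) and RARRES1 (1.40) rose. In MKN-45 RGS4 (5.05 ± 0.15), HEPACAM2 (4.29), the endocrine factor gene RFX6 (3.28), NDP (3.20) and TMEM158 (3.12) rose, while KIF20A (-1.88), DLGAP5 (-1.70), CCNB2 (-1.64), MYO1A (-1.62) and PRIM1 (-1.61) fell. Mitosis genes fell in 22 of 24 cases in EBC-1 (median -0.97, adjusted p = 2.7e-46) and 20 of 24 in MKN-45 (median -0.78, adjusted p = 1.7e-23), and cholesterol synthesis genes rose in 12 of 15 cases in EBC-1 (median 0.41, adjusted p = 9.23e-16). Ribosome biogenesis fell in 18 of 22 cases in HCC827 (median -0.43, adjusted p = 5.31e-12). ER chaperones rose in MKN-45 in 13 of 16 cases (median 0.37, adjusted p = 1.68e-08, and adjusted p = 0.0844 with an estimated correlation). In HCC827 S100P (1.95), SAA2 (1.92), CCL20 (1.72), CXCL6 (1.71) and SLC60A1 (2.06) were higher at 48 h, and MMP1 (-1.59), ABCC9 (-1.30), SPRR1B (-1.24) and MMP9 (-1.23) lower. Called genes numbered 1371 (618 higher, 753 lower) in EBC-1, 3008 (1850 and 1158) in MKN-45 and 3286 (1956 and 1330) in HCC827, where the share of 59.5% higher was 43% with each array centred and 49.8% with array weights. Without HCC827 SGX-523 24 h replicate 3 they numbered 2972, 4919 and 3564, of which 1743 (48.9%) were higher in HCC827, so which direction held more genes there depended on that array as well as on the scaling. Of those 3564 genes, 2314 were called the same way with all arrays. In EBC-1 too, which direction held more genes turned with quantile normalization.

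In DMSO, without the inhibitor, MET was 12.81 ± 0.051 (SD, n = 3) in EBC-1, 12.73 ± 0.11 in MKN-45 and 12.21 ± 0.031 in HCC827, 0.60 ± 0.14 (adjusted p = 0.000481) and 0.52 ± 0.14 (adjusted p = 0.00183) log2 units above HCC827 by the brightest probe set. The other 5 kept probe sets put HCC827 further below, the next brightest at 10.64 ± 0.027 (SD, n = 3) against 12.14 ± 0.040 in EBC-1 and 12.09 ± 0.049 in MKN-45. EGFR was far below HCC827 in both lines (-4.30 in EBC-1 and -3.83 in MKN-45), as were the ligand gene NRG1 (-4.69 and -4.61) and BTC (-3.08 and -3.32). FGFR2 was above HCC827 in MKN-45 (4.25) and IGF1R below it in EBC-1 (-3.14). Of the gastric and intestinal lineage genes, which were not tested as a list in DMSO, TFF1 (6.16) and LGALS4 (6.12) were higher in MKN-45 and CDX1 (-0.997) and PGC (-0.80) lower, while in EBC-1 LGALS4 (2.35) and MUC13 (2.81) were higher and MUC1 (-3.55), TFF1 (-0.77), CDX1 (-0.76) and PGC (-0.54) lower. The lung gene NAPSA was lower in both (-3.57 and -3.44). The lower of the levels compared lay below the array median for FGFR2, IGF1R, BTC and the lineage genes other than NAPSA and MUC1, where sizes are less exact. For TFF1 in EBC-1, and for CDX1 and PGC in both lines, both levels compared lay below the array medians. Their differences went the same way as the median of all genes (-0.482 and -0.49), so their direction is uncertain as well. These comparisons called 10196 genes for EBC-1 (2273 higher, 7923 lower) and 10296 for MKN-45 (2450 and 7846). The median of all genes lay at -0.482 and -0.49, in the direction of the difference in array medians, and with quantile normalization, which moved it to 0.020 and 0.0034, 51.1% and 50.7% of the called genes were higher in place of 22.3% and 23.8%. The sizes given for single genes, MET among them, carry that shift.

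The remaining lists were not called in EBC-1 or MKN-45 against DMSO. Genes of the BCL2 family moved singly, with the BH3-only genes BCL2L11 (1.36 in EBC-1 and 1.59 in MKN-45 at 48 h), BBC3 (1.69 and 1.35) and BMF (3.45 in MKN-45) rising, and list adjusted p of 0.478 and 0.348. Receptor and ligand genes (7 higher and 5 lower of 19 in EBC-1 at 48 h, adjusted p = 0.352; 9 and 7 in MKN-45, adjusted p = 0.974) included the ligand gene EREG (-2.93 in EBC-1) and HBEGF (-2.41 in MKN-45). Epithelial genes (7 and 5 of 15, adjusted p = 0.387; 9 and 4, adjusted p = 0.778) held both OCLN (2.12 in EBC-1) and KRT18 (-1.41 and -2.05). Mesenchymal genes (3 and 2 of 10, adjusted p = 0.885; 1 and 4, adjusted p = 0.377) held SNAI2 (-2.75 in EBC-1) and VIM (-1.16 in MKN-45). Interferon genes (11 and 4 of 23, adjusted p = 0.204; 8 and 6, adjusted p = 0.778) held IFIT2 (2.09 and 1.38), and p53 targets (4 and 6 of 16, adjusted p = 0.558; 7 and 5, adjusted p = 0.478) held GDF15 (-2.22 in EBC-1). Of chemokine genes, CXCL8 fell in EBC-1 (-3.90) and CCL20 rose in MKN-45 (2.80), with list adjusted p of 0.143 and 0.339. Gastric and intestinal lineage genes (0.143 and 0.152) included CDX2, which rose in both lines (3.06 and 2.47), and squamous genes (0.944 and 0.778) SOX2, which rose in MKN-45 (3.06). The lung list (4 genes, 0.728 and 0.974) and the leukocyte list (4 genes, 0.853 and 0.974) were not called. For the fibroblast list 1 gene was measured, LUM (2.02 in EBC-1 and -0.054 in MKN-45), with list adjusted p of 0.228 and 0.971. The median and the mean of a list differed in sign at 48 h for the squamous list in both lines and for the mesenchymal, p53 and leukocyte lists in EBC-1.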

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

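The tests of compressed signal and of the ERK pathway output list in HCC827, and the counts over other splits of the arrays, were chosen after the results were seen.

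The response to SGX-523 differed between cell lines by an interaction test in 6390 genes at 24 h and 6031 at 48 h for EBC-1 against HCC827, in 6525 and 6328 for MKN-45 against HCC827, and in 5218 and 6075 for EBC-1 against MKN-45. EGFR itself differed between EBC-1 and MKN-45 by 1.32 at 24 h and 2.56 at 48 h, rising in 1 line and falling in the other. Probe sets outside the gene tests, 2326 of them with several genes or no gene (1252 with none), also carried a signal, with 1345 called at 48 h in EBC-1, 1332 in MKN-45 and 407 in HCC827.

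HCC827 SGX-523 24 h replicate 3 stood apart, with r of at most 0.967 to the other HCC827 arrays. RNA of EBC-1 or MKN-45 mixed in was argued against, since genes at least 4 log2 units higher in MKN-45 (90 genes) or EBC-1 (71 genes) were not in excess on it (median excess -0.0838 and -0.136). RNA degradation stays open as a candidate explanation, as the log2 3 prime to 5 prime ratio of ACTB was 3.404 against at most 2.44 on the other 8 arrays, though that of GAPDH, 0.161, lay within their range of 0.113 to 0.179. A weak or compressed hybridization signal stays open too, with a slope of 0.952 on the mean of the others, whose own slopes ran from 0.99 to 1.01. The design gives no group for this array alone, and no biological explanation was tested.

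HCC827 at 48 h had higher chemokine and FOXO lists and lower replication and ribosome biogenesis lists than DMSO. The members of the ERK pathway output list went both ways, 3 called higher and 5 lower, with a median of -0.0733. EGR1 and FOS were among those higher, although lower ERK pathway output predicted their fall. This argues against a fall of the whole list, as seen in EBC-1 and MKN-45. Lower output of some members, by changes of the small size seen here, stays open. Of the shared genes of EBC-1 and MKN-45 called in HCC827, 89.5% went the same way, so a smaller response of the kind seen in those lines may be part of it. Time in culture could not be separated from the inhibitor, because 0 of the HCC827 DMSO arrays have a time in the labels, and RNA quality cannot be told apart either, because the ACTB ratio was higher at 48 h by 0.252 in the same arrays, while that of GAPDH differed by -0.00517 (exact permutation p = 0.7). An effect of SGX-523 in this line thus stays open as a hypothesis.

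Reference genes fell with SGX-523 in EBC-1 and MKN-45. A normalization that lowers unchanged transcripts was argued against, because the external control probe sets rose in these comparisons, by between 0.267 and 0.423. In HCC827 they shifted by 0.0392 at 24 h and -0.038 at 48 h. It was not tested whether gene or list rises of about 0.267 to 0.423 in EBC-1 and MKN-45 carry the same shift. RNA quality cannot be told apart from the inhibitor, because the ACTB 3 prime to 5 prime ratio rose with it in all 4 comparisons, by 0.149 to 0.623 (GAPDH by 0.0229 to 0.214), and the groups are confounded with it. A lower output of housekeeping transcripts with the inhibitor stays open as a hypothesis, which was not tested further.

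For comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05, and the real split was 1 of 10 as large in each. The real count and the highest of the other splits were 7336 and 1 (EBC-1 24 h), 7632 and 0 (EBC-1 48 h), 7470 and 0 (MKN-45 24 h), 7757 and 1 (MKN-45 48 h), 4 and 2 (HCC827 24 h) and 2755 and 0 (HCC827 48 h). For 48 h against 24 h they were 1371 and 2 in EBC-1, 3008 and 1 in MKN-45, and 3286 and 301 in HCC827, and for DMSO 10196 and 0 (EBC-1 against HCC827) and 10296 and 0 (MKN-45 against HCC827). For the number of lists called, the splits as large and the real and highest other values were 4 of 10 (13 and 13) and 4 of 10 (14 and 14) in EBC-1 at 24 h and 48 h, 2 of 10 (14 and 14) and 1 of 10 (13 and 12) in MKN-45, and 4 of 10 (1 and 1) and 6 of 10 (5 and 8) in HCC827. Every other split leaves unequal numbers of treated and DMSO arrays on its sides, so part of the response remains in it. The list counts of these splits therefore do not show how many lists would be called without a response.

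For the differences between lines, 100 splits were drawn. A count as large came from 10 of them for EBC-1 against HCC827 at 24 h (6390, highest other 6618), 6 for MKN-45 against HCC827 at 24 h (6525, 6737), 12 for EBC-1 against MKN-45 at 24 h (5218, 8453) and 5 for EBC-1 against HCC827 at 48 h (6031, 7373), so that chance is not excluded for these by this count. It came from 3 for MKN-45 against HCC827 at 48 h (6328, 7147) and 2 for EBC-1 against MKN-45 at 48 h (6075, 8561). Other splits gave more genes than the real one there too, so this count does not exclude chance for these either. All other splits as large kept the treated and DMSO arrays of a responding line apart, so they point to a structure of the samples, the response itself, and the size of such a count says little. Overlaps as large came from 1 split of 100 for genes shared by EBC-1 and MKN-45 at 24 h (4920, highest other 627). The same held at 48 h (4819, 0) and for both times in EBC-1 (6625, 455). Shuffling treated and DMSO arrays within a line breaks up its response, so these splits show only that the lines respond. They cannot tell whether an overlap exceeds that of 2 unrelated responses. For both times in MKN-45 the number of splits as large was 2 (6428, 6634), of which the other kept the treated and DMSO arrays apart. For both times in HCC827 it was 2 (4, 398), and a split with many times the real count points to a structure of the samples there, where 1 treated array stands apart.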

How the results depend on the processing

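Array weights, and leaving out HCC827 SGX-523 24 h replicate 3 in the other comparisons, were chosen after seeing the data, and the other alternatives before. The counts of called genes in EBC-1, MKN-45 and their overlaps stayed within 1.5 times under all of these, except for 48 h against 24 h. With 1 array left out they ran from 6929 to 8374 (EBC-1 24 h), 7164 to 8682 (EBC-1 48 h), 7015 to 8470 (MKN-45 24 h) and 7270 to 8751 (MKN-45 48 h). The count of 4 in HCC827 at 24 h, the 4 genes called at both times and the 1 list called depended on most settings. They became 27, 24 and 2 with quantile normalization, 11, 9 and 3 with a pseudocount of 64, 1, 1 and 4 without a filter, and 82, 65 and 4 with array weights. They became 0, 0 and 3 with no intensity trend, the replicate block or the mean of all probe sets, and 0, 0 and 2 with a separate fit per line. Centring gave 37 and 31 genes, a pseudocount of 1 gave 1 and 1, and the stricter filter and the estimated correlation gave 0 lists. With 1 array left out the ranges were 0 to 2675 genes, 0 to 482 at both times and 0 to 4 lists. Other counts moved with array weights (HCC827 48 h 5362, EBC-1 48 h against 24 h 2818), the separate fit (HCC827 48 h 1217, 48 h against 24 h 2828 in EBC-1 and 1059 in HCC827) and without the array that stands apart (HCC827 48 h 4649, 48 h against 24 h 2972 in EBC-1 and 4919 in MKN-45). That array widens the shared estimate of the spread (residual SD 0.367), and for the remaining moves the cause was not tested. With 1 array left out, HCC827 at 48 h ran from 2039 to 4649, and 48 h against 24 h from 991 to 2972 in EBC-1 and 2352 to 4919 in MKN-45. GAPDH in place of ACTB gave 3 prime to 5 prime differences of 0.0229, 0.0861, 0.0581 and 0.214 in EBC-1 and MKN-45, and in HCC827 at 48 h the sign reversed to -0.00517.

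Among named genes, the mean of all probe sets reversed HMGCS1 in EBC-1 at 24 h (-0.062) and MKN-45 at 48 h (-0.14), INSIG1 (-0.23), ITGB1 (-0.097) and VIL1 (0.57) in MKN-45 at 48 h, and MCL1 in EBC-1 at 24 h (-0.092) and 48 h (-0.084), MKN-45 at 48 h (-0.11) and HCC827 at 48 h (-0.018), by its construction from probe sets that disagree. Without a filter TRAF1 in MKN-45 at 24 h reversed (-0.47), and the cause was not tested. Over all settings other than a left-out array, 20569 values of named genes kept their direction and side of the threshold, 281 passed it newly, 218 no longer passed and 10 reversed. With an array left out the numbers were 12722, 250, 230 and 0. For lists they were 1889, 28, 21 and 0, and 1089, 12, 6 and 0. The share of called genes that were higher depended on the scaling in several comparisons. With centring it went from 59.5% to 43% for 48 h against 24 h in HCC827 (48.9% without 24 h replicate 3 and 49.8% with array weights), from 57.7% to 46.8% for MKN-45 minus HCC827 at 24 h, from 43.6% to 51.7% and from 40% to 49.6% for EBC-1 minus MKN-45 at 24 h and 48 h, and from 22.3% to 52% and 23.8% to 50.7% for DMSO of EBC-1 and MKN-45 against HCC827. With quantile normalization it went from 45.1% to 51.3% for 48 h against 24 h in EBC-1. In HCC827 at 24 h, where 100% of 4 genes were higher, it was 31.7% and 30.8% without treated replicate 1 or 2. In HCC827 at 48 h the share of 52% fell to between 49% and 49.8% with a pseudocount of 64, the mean of all probe sets, array weights, or DMSO replicate 3 or 24 h replicate 3 left out, and in EBC-1 at 48 h that of 53.2% fell to 49.6% with the stricter filter. Replicate numbers were not taken as pairs, since deviations of same-numbered arrays had r between -0.197 and 0.159. Low signal over background limits genes such as HGF, which were not tested.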

Other observations

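The family scan and the list of genes with opposite changes were chosen after the data were seen, and the test of converging lines was written after such genes had been listed. Gene families were scanned by the stem of their symbols, 137 families with at least 10 genes. Members of the 27 lists were not left out. Mitochondrial ribosomal protein genes of the large subunit (48 MRPL genes) fell in 37 cases in EBC-1 at each time (medians -0.49 and -0.60), in 34 and 37 in MKN-45 (-0.35 and -0.39), with between 1 and 4 higher, and in 16 in HCC827 at 48 h (-0.14, adjusted p = 6.06e-07). At 24 h in HCC827 their median was 0.0030 (adjusted p = 0.685). Of 374 zinc finger (ZNF) genes, 154 rose and 52 fell in EBC-1 at 24 h (camera adjusted p = 0.0244) and 166 and 55 at 48 h (adjusted p = 0.0523, not called), and in MKN-45 209 and 32 (adjusted p = 0.00044) and 232 and 26 (adjusted p = 3.4e-05). Vacuolar sorting genes (35 VPS genes) had medians of 0.43 (adjusted p = 0.0194) and 0.45 (adjusted p = 0.058, not called) in EBC-1, and 0.52 (adjusted p = 0.0088) and 0.46 (adjusted p = 0.00728) in MKN-45. These directions were the same with quantile normalization and centring. The ZNF and VPS rises were not set apart from the rise of the external controls on these arrays, 0.267 to 0.423. With an estimated correlation the MRPL, ZNF and VPS families were not called in any comparison (adjusted p between 0.149 and 0.655 where the preset test called them). By that test 2 families were called in EBC-1 at 24 h, both lower, KIF (adjusted p = 0.0378) and PSMD (adjusted p = 0.0434). At 48 h in EBC-1 it called 1, KIF (lower, adjusted p = 0.039), and 0 in the other comparisons.

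Some genes, chosen after their values were seen, were called in opposite directions in EBC-1 and MKN-45 at 48 h. PDGFA, a growth factor gene, was at -2.13 ± 0.074 in EBC-1 and 2.62 in MKN-45, and the neuronal tubulin gene TUBB3 at -2.40 and 1.59. The other way went SERPINB5 (1.96 and -2.12), S100P (2.91 and -1.78), the transcription factor gene KLF4 (2.14 and -1.50), GPX2 (1.39 and -2.46) and LGALS4 (1.30 and -1.37). Of the 852 such genes, 363 were higher with SGX-523 in EBC-1 and 489 in MKN-45.

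A hypothesis was that with the inhibitor the lines become more alike in these genes. Of the 250 such genes in the test, 164 (65.6%) fell in the line with the higher DMSO level, which is consistent with it for these genes. Genes that start high have more room to fall, which this test does not separate. Over all genes the mean absolute difference between the lines went from 0.789 in DMSO to 0.906 at 48 h, and r from 0.822 to 0.78, so the lines did not become more alike as a whole.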
